A study of Mus musculus with 6 samples.

How the data were processed

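Trigeminal ganglia of wild-type mice were profiled by bulk RNA sequencing in 6 libraries, 3 from the vehicle group and 3 from the NTG group. Groups and replicate numbers were taken from the sample labels. RNA was extracted with TRIzol, enriched for polyadenylated transcripts on poly-T beads, made into strand-specific libraries with a NEBNext Ultra kit and sequenced in paired ends on a NovaSeq instrument, per the labels' protocols. Reads were checked with FastQC and aligned to GRCm38 with HISAT2, per the submitters' processing notes. The counting tool, its strand setting, the annotation and the normalization tool are not given in the sources used here. If reads were counted without regard to strand, a gene and an overlapping gene on the opposite strand cannot be told apart, and genes with near-identical copies can share reads.

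The deposited table held 1 value per gene and library, a signal made of gene counts divided by a size factor, for 17524 genes (15116 protein-coding, 2198 long non-coding and 210 of other types). Low values in each library were whole multiples of what 1 read is worth (0.867 to 1.10), and 100% of values were whole within a tolerance of 0.01 after division by that step, so whole reads were recovered. The libraries held 18813027, 20191300 and 18825239 reads in vehicle and 19293926, 19248592 and 23774244 in NTG. At these depths 3 reads correspond to 0.126 to 0.159 CPM, which covers counting error only. The smallest total of any gene over the 6 libraries was 24 reads. No mitochondrially encoded protein-coding gene was tested, so that list was not analysed here. Coordinates are those of the deposited table, on GRCm38, and 17523 genes had the same chromosome, start and end in the RefSeq gene table used. Transcript GC content and length were matched for 16327 genes (93.2%).

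Before the data were examined, the tests, the gene lists, the named-gene rule and most alternatives were fixed. A count test in edgeR had been planned as the main test. Because the values were normalised, its written replacement was used: limma-trend with robust empirical Bayes on log2(value + 1), two-sided, for the 17475 genes with a value of at least 1 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale, which can understate or overstate the change of low genes. For Myh4 the log2 fold change was -2.75, against -3.17 in edgeR on the recovered reads. For Clec9a it was 1.80, against 1.56. Means ± SD are of the deposited values. The quasi-likelihood test of edgeR on the recovered reads called 4658 genes. Nothing says that the replicates are separate animals, so p-values measure the spread between these samples.

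Named genes were the 8 genes of the series title and the CGRP receptor, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM, a symbol of their own and no overlap between groups, and up to 4 members of each gene list with the smallest p. Some genes that the rule chose are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Of 42 gene lists written from textbook knowledge, 40 were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The list of sex-linked genes served only to check the samples. Members that rose or fell were counted over all genes tested and adjusted over the list alone. The level of a list in a library is the mean log2 CPM of its members with 0.5 CPM added, compared by exact two-sided permutation, whose smallest p is 0.1.

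Alternatives covered the pseudocount, filters, scaling, DESeq2, limma-voom, a minimum fold of 1.2, the replicate number as a block and each library left out in turn. Those chosen after seeing the data were edgeR on recovered reads, the removal of each library's smooth trend over transcript GC content and log2 length (mgcv) with the results that build on it, and the omission of genes opposite a 20-fold higher gene. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 4.10 to 7.99), so none was counted as a duplicate.

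The scripts were tested on simulated data for this comparison, with 200 changed genes among the real ones. Of 1.5-fold changes, limma called 74% with the right sign over 17493 genes tested, 96.6% at 20 CPM or more and 42.9% below; of 2-fold changes it called 75%, 100% and 49.0%. Unchanged genes were 8.59% of the calls, and 0 genes were called where none had been changed. With the observed GC slopes added, 2406 genes were called without the adjustment and 163 with it. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, mgcv 1.9.3, GenomicRanges 1.54.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.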

Results

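Messenger RNA was profiled in the trigeminal ganglion of wild-type mice, the sensory ganglion whose neurons supply the face and the meninges and release calcitonin gene-related peptide (CGRP) in migraine models. The comparison was between 3 libraries from vehicle-treated mice and 3 from mice given NTG. The labels use only this abbreviation, which in mouse migraine work commonly stands for nitroglycerin, a nitric oxide donor that triggers headache. The table held normalised read counts of 17524 genes, from which whole reads were recovered. Vehicle replicates 1 to 3 held 18813027, 20191300 and 18825239 reads, and NTG replicates 1 to 3 held 19293926, 19248592 and 23774244. The first principal component held 36.5% of the variance and placed the 3 NTG libraries on one side and the 3 vehicle libraries on the other.

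The series title names SETDB2, KLF4, IDE and CGRP, so the genes of this axis were compared first between NTG and vehicle. Ide encodes insulin-degrading enzyme, a peptidase that cleaves several peptide hormones. It fell from 2271 ± 178 normalised reads in vehicle to 1397 ± 77.3 in NTG (SD, n = 3 each), and was lower in all 3 NTG libraries. The log2 fold change was -0.70 ± 0.07 (SE, limma adjusted p = 1.94e-06). Setdb2, a member of the histone H3 lysine 9 methyltransferase family, rose from 78.7 ± 2.25 to 124 ± 15.7 normalised reads (log2 fold change 0.65 ± 0.18, limma adjusted p = 0.0126). Klf4, a Kruppel-like transcription factor, stood at 155 ± 18.3 in vehicle and 120 ± 14.0 in NTG, and did not pass the test (log2 fold change -0.37 ± 0.17, limma adjusted p = 0.110). Neither CGRP gene passed. Calca, which encodes the alpha form, stood at 8849 ± 600.5 and 9620.2 ± 659.6 normalised reads (log2 fold change 0.12 ± 0.06, limma adjusted p = 0.140). It passed only without NTG replicate 1 when libraries were left out in turn (log2 fold change 0.18, limma adjusted p = 0.0329; 0.16 and 0.0328 after adjustment for GC content and length), and its adjusted p over all alternatives lay between 0.0305 and 1. Calcb, which encodes the beta form, stood at 1126 ± 67.0 and 1047 ± 13.4 (log2 fold change -0.10 ± 0.07, limma adjusted p = 0.311). The receptor genes Calcrl (log2 fold change 0.40 ± 0.17, limma adjusted p = 0.0907), Ramp1 (-0.54 ± 0.29, 0.189) and Crcp (-0.00 ± 0.09, 0.995) did not pass either. Of the 8 genes of this list, 1 rose and 1 fell over all genes tested, and 1 rose and 1 fell adjusted over the list alone. Because the study may have chosen some of them from these libraries, their direction is not independent evidence.

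On GRCm38, the file places Setdb2 on chromosome 14 (59402009 to 59440880, minus strand), Klf4 on chromosome 4 (55527137 to 55532475, minus) and Ide on chromosome 19 (37268743 to 37334544, minus). Calca lies on chromosome 7 (114625981 to 114636910, minus) and Calcb on the same chromosome (114716555 to 114723368, plus). Setdb2 overlaps the predicted gene Gm45935 on the same strand, which was listed at 1.13 times its level, and reads of these genes cannot be told apart where they overlap. Gm45935, named here after its values were seen, also rose, from 89.5 ± 13.2 to 139 ± 12.3 normalised reads (log2 fold change 0.64 ± 0.18, limma adjusted p = 0.0115). The fall of Ide passed under all 31 alternatives run, with log2 fold changes between -0.92 and -0.63. The rise of Setdb2 did not pass without NTG replicate 1 (limma adjusted p = 0.0673), without NTG replicate 2 (0.0907) or against a minimum fold of 1.2 (0.387). It did not pass either after each library's trend over transcript GC content and length was removed (log2 fold change 0.44, limma adjusted p = 0.136). Its adjusted p over all alternatives lay between 0.0105 and 0.430.

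**Figure D1:**
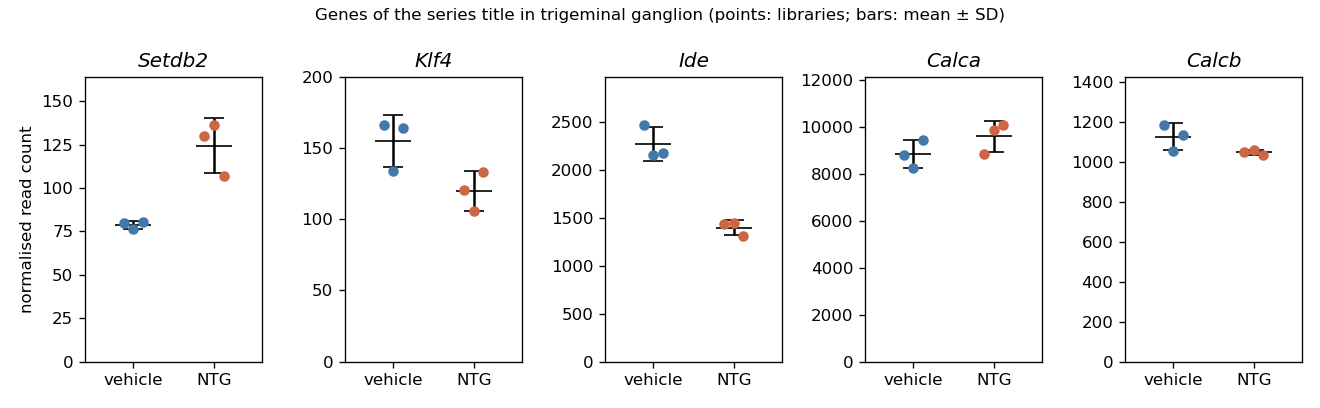
Normalised read count (vertical axes, from 0) of Setdb2, Klf4, Ide, Calca and Calcb in the 3 vehicle and 3 NTG libraries; points are libraries and bars are the mean ± SD. The 3 NTG values of Ide lie between 1308 and 1447, below the vehicle values of 2157 to 2476, and those of Setdb2 between 107 and 137, above the vehicle values of 76.2 to 80.4.

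Among genes past the threshold with a symbol of their own, a mean of at least 1 CPM and no overlap between groups, the largest fall belonged to Bc1, a small brain cytoplasmic RNA of neurons, which went from 943 ± 89.5 normalised reads in vehicle to 20.8 ± 10.1 in NTG (SD, n = 3 each). It was 47.3-fold lower in NTG (log2 fold change -5.57 ± 0.37, limma adjusted p = 6.56e-05). Genes of fast skeletal muscle were among the next: Myh4 (a fast myosin heavy chain) was 6.74-fold, Atp2a1 (a calcium pump of the sarcoplasmic reticulum) 3.28-fold and Ckm (muscle creatine kinase) 3.23-fold lower in NTG. Other large falls were those of the transcription factor Sox3 (64.3 ± 8.51 to 18.2 ± 6.68 normalised reads), Ifi208 (33.2 ± 9.74 to 8.63 ± 3.09), Ifitm7 (210 ± 22.6 to 73.0 ± 0.876), and Capn12 (86.4 ± 13.0 to 24.7 ± 5.90). Bricd5, Kcnmb4os1, Ager and the globin gene Hba-a2 completed the 12 largest falls. On the other side, Plin4, which encodes a lipid droplet protein, rose from 60.8 ± 28.5 to 167 ± 10.5 normalised reads (log2 fold change 1.53 ± 0.24, limma adjusted p = 0.000166). Cdr1, listed as a protein-coding gene at the locus of an abundant circular RNA of neurons, rose from 374 ± 27.2 to 897 ± 64.2 (log2 fold change 1.26 ± 0.09, limma adjusted p = 3.23e-08). Whether its reads came from the circular RNA was not tested. Ubb-ps, a ubiquitin pseudogene, rose from 558 ± 65.4 to 1483 ± 243. Clec9a, a dendritic cell receptor, rose from 16.9 ± 11.1 to 50.1 ± 3.30 and the stress-induced pseudokinase gene Trib3 from 33.1 ± 17.2 to 68.9 ± 11.8. The mitochondrial transfer RNA TrnM, Kif24, Fsbp, Nusap1, Zfp953 and Yy2 were also among the 12 largest rises.

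The 24 genes with the largest changes had 3 NTG values that did not overlap the 3 vehicle values, as required by the rule that chose them. Some counts are uncertain: Ubb-ps, Hba-a2, Ifi208 and Zfp953 have near-identical relatives. Bc1 (chromosome 7, 144914470 to 144914623) and TrnM (chromosome M, 3845 to 3913) are short genes. How evenly libraries enriched on poly-T beads recover such RNAs was not tested, so their changes may not be changes in expression. Yy2 lies within Mbtps2, which was listed at 16.7 times its level on the same strand, and Fsbp and Zfp953 overlap same-strand genes. Capn12, Bricd5, Atp2a1, Ifitm7, Plin4 and Kcnmb4os1 lie opposite a gene at 81.2, 24.9, 21.6, 17.5, 9.76 and 9.21 times their level. Of the 22 genes with a known transcript GC content, 5 of 10 rises and 10 of 12 falls passed after the GC and length trends were removed. Among those that did not were Fsbp, Nusap1, Zfp953, Yy2, Hba-a2 and Ager. With libraries left out in turn, these genes, Kif24 and Trib3 each missed the threshold at least once. The highest limma adjusted p was reached without NTG replicate 1 for Fsbp (0.163), Kif24 (0.0969) and Yy2 (0.131), without NTG replicate 2 for Trib3 (0.0841), Zfp953 (0.133), Hba-a2 (0.141) and Ager (0.0865), and without NTG replicate 3 for Nusap1 (0.0784).

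**Figure D2:**
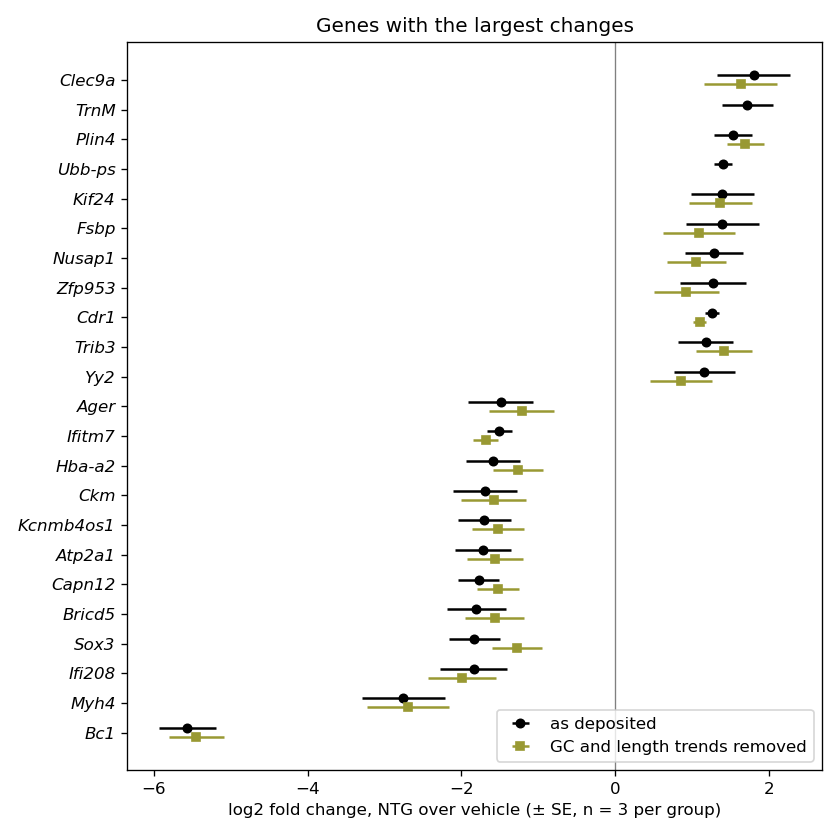
Log2 fold change of NTG over vehicle (horizontal axis, ± SE, n = 3 per group) of the genes named among the 12 largest rises and 12 largest falls, as deposited (circles) and after GC and length adjustment (squares, absent for TrnM and Ubb-ps). Bc1 lies apart at -5.57, and the other genes lie between -2.75 and 1.80.

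In all, 4512 of 17475 genes passed the threshold (limma-trend, adjusted p under 0.05), of which 2148 rose and 2364 fell in NTG. Most changes were small: 210 genes rose and 474 fell by at least 1.5-fold, and 313 passed a test against a minimum fold of 1.2 (77 up, 236 down). Groups did not overlap in 39.7% of the genes, against 10% by chance. The count test of edgeR on the recovered reads called 2317 rises and 2341 falls, and 4448 genes were called by both tests in the same direction. Nothing in the labels says that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical. Without NTG replicate 2, 2945 genes passed.

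The direction of a change followed the base composition of the transcript. In the tenth of protein-coding genes with the lowest GC content (median 40.2%), the median log2 fold change was 0.32, with 684 rises and 16 falls. In the tenth with the highest (median 60.1%), it was -0.31, with 1 rise and 834 falls. Spearman's rho between log2 fold change and GC content was -0.64 across 14932 protein-coding genes, which are not independent replicates. The slope of a library's deviation over GC content was positive in the 3 vehicle libraries (0.11, 0.18 and 0.15 log2 units per 10 percentage points). It was negative in the 3 NTG libraries (-0.21, -0.17 and -0.08; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). After removal of the trends over GC content and length from each library, an adjustment chosen after seeing the data, 1565 of 16278 genes passed (737 up, 828 down), and 1058 of these had been called in the same direction before. Counts of members after this adjustment are therefore given beside those of each gene group below, and can include members not called before it.

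**Figure D3:**
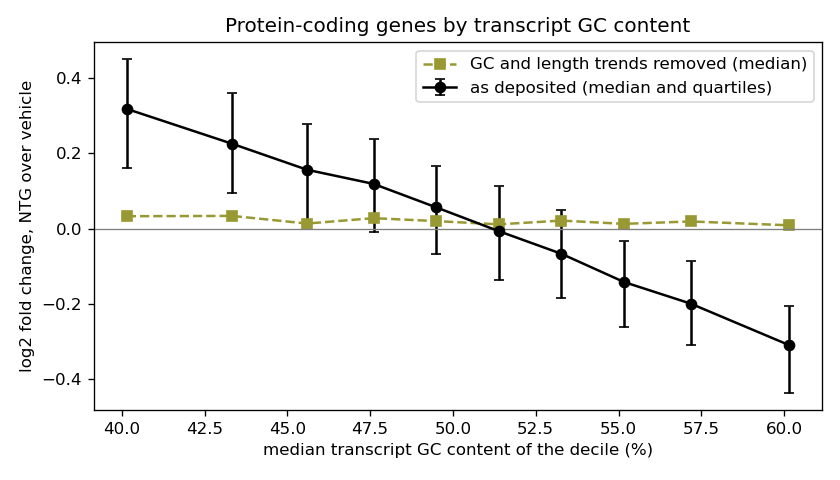
Median log2 fold change of NTG over vehicle (vertical axis) in 10 classes of protein-coding genes by transcript GC content (horizontal axis, %), with quartiles as bars for the values as deposited (circles) and medians after removal of the GC and length trends (squares). The medians as deposited go from 0.32 to -0.31.

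Immediate early genes, the transcription factors and regulators induced within minutes of neuronal activity, were lower in NTG: of 27 tested, 0 rose and 11 fell over all genes tested, and 11 fell adjusted over the list alone. Egr1 fell from 377 ± 30.3 to 237 ± 23.1 normalised reads, Egr3 from 300.4 ± 44.3 to 168 ± 31.0, Ier5 from 337 ± 16.6 to 217 ± 14.0 and Jund from 6267 ± 718 to 3879 ± 419.7. The list passed camera (adjusted p = 0.00461), but not with an estimated correlation (adjusted p = 0.919). After the GC and length adjustment 3 members fell, Egr1, Egr3 and Ier5 with log2 fold changes of -0.46, -0.82 and -0.58, while Jund did not pass (-0.12, limma adjusted p = 0.126). The list passed camera after it (adjusted p = 0.0215; adjusted p = 0.77 with an estimated correlation), but not without vehicle replicate 2 (0.112).

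Skeletal muscle markers, which a ganglion should lack and dissection can carry in, were lower in NTG: 7 of 14 fell and 0 rose, 7 also adjusted over the list alone. Besides Myh4, Atp2a1 and Ckm, Tnni2 fell from 17.2 ± 3.94 to 2.34 ± 0.726 normalised reads. The list passed camera (adjusted p = 0.0216; adjusted p = 0.919 with an estimated correlation), and its mean level was 1.09, 1.15 and 1.43 log2 CPM in vehicle against 0.56, 0.58 and 0.51 in NTG (exact two-sided permutation p = 0.1). It did not pass camera without vehicle replicate 3 (adjusted p = 0.0545), without NTG replicate 3 (0.072) or with genes under a mean of 1 CPM left out (0.341). After the GC and length adjustment 5 fell and the list passed camera (adjusted p = 0.00327; adjusted p = 0.77 with an estimated correlation).

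Interferon-stimulated genes passed camera (adjusted p = 2.53e-05; adjusted p = 0.919 with an estimated correlation). Their median log2 fold change was -0.59 over 28 genes, but only 4 members fell over all genes tested and 2 adjusted over the list alone. The antiviral ubiquitin-like gene Isg15 fell from 256 ± 125 to 94.8 ± 4.81 normalised reads, Ifi44 from 64.4 ± 51.0 to 21.6 ± 5.19. Zbp1 fell from 67.1 ± 48.6 to 24.4 ± 1.59, and Ifi27 from 3354 ± 511 to 2655 ± 181. The vehicle libraries differed among themselves, with list levels of 4.73, 3.90 and 3.24 log2 CPM against 3.37, 3.23 and 3.29 in NTG (exact two-sided permutation p = 0.3). Without vehicle replicate 1 the list did not pass camera (adjusted p = 0.0572), and neither Ifi44 (limma adjusted p = 0.177) nor Zbp1 (0.193) passed. Isg15 and Ifi27 did not pass without NTG replicate 1 (limma adjusted p = 0.0728 and 0.0751). After the GC and length adjustment 1 member fell, Ifi44, and the median log2 fold change was -0.71. The list then passed camera (adjusted p = 1.98e-11; adjusted p = 0.77 with an estimated correlation), also without vehicle replicate 1 (9.4e-05).

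**Figure D4:**
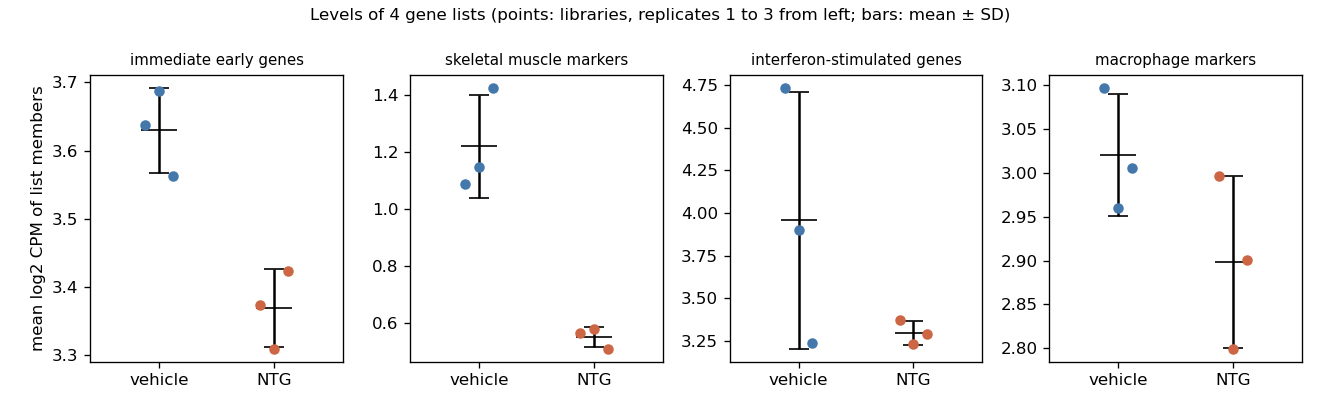
Mean log2 CPM of the members (vertical axes, which do not start at 0) of 4 gene lists in the 3 vehicle and 3 NTG libraries; points are libraries and bars the mean ± SD. Immediate early genes and skeletal muscle markers are lower in each NTG library than in any vehicle library, interferon-stimulated genes are high in vehicle replicates 1 and 2, and macrophage markers overlap.

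No other list of the 40 tested passed camera on the values as deposited, so the groups below are described by their members. Of all 17475 genes tested, 2148 rose and 2364 fell. After the GC and length adjustment 737 of 16278 rose and 828 fell. Member counts near these shares do not set a list apart from genes at large. Among sensory neuron genes, Map2 rose while Rbfox3 and Pou4f1 fell (log2 fold changes 0.36, -0.53 and -0.41). All 3 passed again after the GC and length adjustment (0.27, -0.28 and -0.44). Of 18 pan-neuronal genes 4 rose and 5 fell, 4 and 6 adjusted over the list alone, and 4 and 4 after the GC and length adjustment. Of 23 markers of non-peptidergic nociceptors and itch neurons 4 rose and 0 fell, the same counts as adjusted over the list alone, and 3 and 0 after the GC and length adjustment. Among them were the oncostatin M receptor gene Osmr (279 ± 28.9 to 406 ± 13.5 normalised reads), the itch receptor gene Mrgprx1 (69.9 ± 11.01 to 115 ± 3.20) and the neurotensin gene Nts (48.7 ± 19.9 to 99.4 ± 23.9). Osmr and Mrgprx1 passed after the adjustment and Nts did not, nor did Nts without NTG replicate 1 (limma adjusted p = 0.0677). The level of this list was higher in each NTG library (4.86, 4.88 and 4.86 against 4.67, 4.69 and 4.65 log2 CPM, exact two-sided permutation p = 0.1). The median log2 fold change of the list was 0.11 before the GC and length adjustment and 0.05 after it. Of 17 peptidergic nociceptor markers 3 rose and 2 fell, also adjusted over the list alone, and after the GC and length adjustment 1 rose and 0 fell. Tac1, which encodes substance P, rose by a log2 fold change of 0.30 (0.19 after the adjustment, limma adjusted p = 0.0462). The irritant channel gene Trpa1 rose by 0.41 (0.20 after it, limma adjusted p = 0.108).

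Among 32 sodium, calcium and potassium channel genes of sensory neurons 7 rose and 5 fell, 7 and 6 adjusted over the list alone, and after the GC and length adjustment 4 rose and 1 fell. Scn9a, which encodes a voltage-gated sodium channel alpha subunit, rose from 5585 ± 162 to 7530 ± 392 normalised reads, and Scn1a, another such gene, from 3223 ± 187 to 4239.7 ± 217. Both passed after the adjustment. The pacemaker channel gene Hcn2 (5343 ± 456 to 3431 ± 401) fell, and did not pass after the adjustment. Of 21 genes of nitric oxide and cyclic GMP signalling 5 rose and 2 fell, the same adjusted over the list alone, and 1 rose and 0 fell after the adjustment. The phosphodiesterase gene Pde1c (log2 fold change 0.45), Hif1a (0.40), the cyclic GMP-dependent kinase gene Prkg1 (0.34) and the guanylyl cyclase subunit gene Gucy1a2 (0.50) rose, and of these 4 only Pde1c passed after the adjustment (0.22, limma adjusted p = 0.0262). Of 22 targets of migraine drugs and triggers 0 rose and 1 fell, Adcyap1r1, the PACAP receptor gene (361 ± 5.72 to 288 ± 31.6 normalised reads), and 0 passed adjusted over the list alone or after the GC and length adjustment. Adcyap1r1 passed only without vehicle replicate 1 when libraries were left out in turn (limma adjusted p between 0.0458 and 0.177).

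Of 17 peptidases that cleave neuropeptides 4 rose and 2 fell, also adjusted over the list alone, and after the GC and length adjustment 2 rose and 1 fell. Besides the fall of Ide, the aminopeptidase gene Lnpep rose from 1369 ± 154 to 2363 ± 143 normalised reads, the prohormone convertase gene Pcsk1 from 1326 ± 48.6 to 1976 ± 12.8. The neprilysin gene Mme rose from 1126 ± 56.1 to 1506 ± 70.4. Lnpep and Pcsk1 passed after the adjustment and Mme did not. Of 23 enzymes and readers of histone H3 lysine 9 methylation 7 rose and 3 fell, the same adjusted over the list alone, but 2 rose and 2 fell after the adjustment. Beside Setdb2, the demethylase gene Kdm7a (log2 fold change 0.49) and the heterochromatin protein gene Cbx5 (0.36) rose, and the demethylase gene Kdm1a fell (-0.51). After the adjustment Kdm1a passed (-0.48, limma adjusted p = 0.00021), and Kdm7a and Cbx5 did not. Of 14 Kruppel-like factors 0 rose and 5 fell, 6 adjusted over the list alone and 1 after the adjustment. Among them were Klf2 (434 ± 93.8 to 269 ± 35.5 normalised reads) and Klf9 (2626 ± 120.4 to 2319 ± 55.4). Klf9 passed after the adjustment and Klf2 did not, but Klf9 missed the threshold without any 1 of 4 libraries (limma adjusted p of up to 0.122, without vehicle replicate 2). After the adjustment the list passed camera (adjusted p = 0.0361; adjusted p = 0.77 with an estimated correlation), but not without vehicle replicate 2 (0.0944), vehicle replicate 3 (0.0794) or NTG replicate 2 (0.0574).

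Of 16 satellite glia markers 6 rose and 3 fell, also adjusted over the list alone, but after the GC and length adjustment 1 rose and 2 fell and the median log2 fold change went from 0.06 to -0.02. Cdh19 rose from 872 ± 101 to 1498 ± 92.6 normalised reads, Fabp7 fell from 3046 ± 294 to 2418 ± 210, and both passed after the adjustment. The falls of Sox10 (5857 ± 429 to 4202 ± 55.6) and Apoe (73887 ± 1686 to 60741 ± 3491) did not, Apoe with a log2 fold change of 0.00 after it. In non-myelinating Schwann cell markers 2 rose and 3 fell of 10, as adjusted over the list alone, and 2 and 2 after the adjustment, with rises of Scn7a (log2 fold change 0.56, 0.27 after the adjustment) and Matn2 (0.38, 0.37). Of 18 macrophage markers 0 rose and 3 fell, also adjusted over the list alone, and 2 fell after the adjustment. The 3 were the complement genes C1qa, C1qb and C1qc (log2 fold changes -0.55, -0.49 and -0.82), of which C1qc passed after the adjustment. The level of the macrophage list was lower in NTG by 0.12 log2 CPM as a mean and higher by 0.31 as a median over its members. The levels of 18 lists of cell types and other tissues were compared by an exact two-sided permutation test. Of these, 4 reached its smallest p of 0.1, which chance gives in 10% of lists. These were pan-neuronal genes (lower in NTG by 0.04 log2 CPM as a mean, higher by 0.03 as a median), non-peptidergic nociceptor and cold-sensing neuron markers (higher by 0.20 and 0.23) and skeletal muscle markers (lower by 0.67). These levels were not adjusted for GC content and length. Of the 5 cold-sensing neuron markers 1 rose and 0 fell, also adjusted over the list alone, and 0 passed after the adjustment (median log2 fold change 0.23 before and 0.11 after).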

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

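The alternatives with the GC adjustment, edgeR on recovered reads and the omission of genes opposite a 20-fold higher gene were chosen after the result was seen, and the other alternatives given here were planned. Of 4512 genes past the threshold, other pseudocounts, filters, scalings and tools gave 4352 to 4676, with rises between 47.2% and 51.1% of calls; a threshold of 0.1 gave 5765. Against a minimum fold of 1.2, 313 genes passed, and 1 of the 5 title genes, Ide, in place of 2. With libraries left out in turn 2945 to 4670 genes, 1 to 2 title genes and 2 to 5 lists passed, the lowest gene count without NTG replicate 2. After GC and length adjustment 1565 genes, 1 title gene and 6 lists passed, after GC adjustment alone 1495 genes and 1 title gene. With libraries left out in turn after GC and length adjustment, 776 (NTG replicate 2), 1026, 1109, 1129, 1608 and 1625 genes, 1 to 2 title genes (Ide, and Calca without NTG replicate 1) and 4 to 8 lists passed. The replicate numbers did not pair the samples: residuals of same-numbered libraries correlated at 0.004, -0.033 and -0.025, and 0 of the numbers matched best both ways. With the replicate block 5254 genes, 3 title genes and 2 lists passed, with Calca as the added title gene (adjusted p = 0.0305), while skeletal muscle markers (camera adjusted p = 0.0512) and Ifi27 (limma adjusted p = 0.196) did not, and with GC and length adjustment and the block 2210 genes and 1 title gene. With an estimated correlation 0 lists passed, also 0 after GC and length adjustment; fry called 2 and camera on ranks 3. By the median over members, 7 of 18 lists of cell types and tissues reached the smallest exact p, in place of 4. Over the 176 genes of the rule and all alternatives, 4359 of 5388 comparisons stayed on the same side of the threshold, 896 lost the call, 48 gained one and 85 changed sign with a call before or after; sign changes without any call are among the 4359. Of the genes named in the text, Apoe (log2 fold change -0.28) went to 0.0013 after GC and length adjustment, with or without the block, to 0.0036 after GC adjustment alone, and to 0.0042, 0.0095 and 0.0216 with libraries left out after GC and length adjustment. Values of the adjusted fits differ because the GC trend was removed; of the other changes the cause was not tested. Low genes were called less often: 42.9% of simulated 1.5-fold changes under 20 CPM were called, against 96.6% at 20 CPM or more. Depth itself was not varied in the simulation.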

Other observations

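Tests chosen after the result was seen were those of the GC and length adjustment as the source of calls, of the slopes per library, and of vehicle replicate 1 and macrophages for the interferon-stimulated genes. Several chaperone genes rose in NTG: of 22 heat shock and unfolded protein genes 7 rose and 2 fell, 9 and 2 adjusted over the list alone, and 6 and 1 after the GC and length adjustment. Hspd1, a mitochondrial chaperonin, rose from 3138 ± 166 to 4173 ± 90.8 normalised reads (SD, n = 3 each), Hsp90b1 from 5468 ± 429 to 7231 ± 415 and Hsp90aa1 from 18962 ± 1284 to 23789 ± 1282. All 3 passed limma again after the adjustment. The list passed camera only after that adjustment (adjusted p = 0.0215; adjusted p = 0.77 with an estimated correlation), and then not without vehicle replicate 1 (0.0831), vehicle replicate 2 (0.0944) or NTG replicate 3 (0.106). Of 18 clock genes 4 rose and 5 fell, also adjusted over the list alone, but 4 rose and 1 fell after the adjustment. Dbp, an output gene of the clock, rose from 351 ± 11.7 to 575 ± 95.1, and Nr1d2 from 1018 ± 87.8 to 1588 ± 151, and both passed after the adjustment. Per1 fell from 1452 ± 175 to 1103 ± 60.7 but did not pass after the adjustment. Of 22 glucocorticoid-responsive genes 2 rose and 7 fell, 2 and 8 adjusted over the list alone and 1 and 5 after the adjustment, with falls of Cebpd (log2 fold change -0.69), Ddit4 (-0.71) and Nfkbia (-0.53) that passed after the adjustment.

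Of 30 nuclear-encoded oxidative phosphorylation genes 4 rose and 10 fell, 5 and 11 adjusted over the list alone, and 3 and 5 after the GC and length adjustment. Cox7c fell from 2311 ± 32.5 to 1542 ± 74.1 normalised reads and Uqcrq from 1914 ± 49.4 to 1350.4 ± 60.0. Of 38 ribosomal protein genes 5 rose and 9 fell, the same adjusted over the list alone, but 10 rose and 4 fell after the adjustment, and the list did not pass camera before or after it. Rps28 (log2 fold change -0.78), Rpl38 (-0.69), Cox7c and Uqcrq fell also after the adjustment. Of 18 fibroblast and meningeal markers 1 rose and 6 fell, 3 and 6 adjusted over the list alone, and 1 and 5 after the adjustment. Ogn rose (0.60), Col1a2 (-0.36) and Foxc1 (-0.67) fell, and all 3 passed after the adjustment. This list passed camera only after the adjustment (adjusted p = 0.0327; adjusted p = 0.77 with an estimated correlation), and then not without vehicle replicate 3 (0.206) or NTG replicate 2 (0.196). Of 365 zinc finger genes named Zfp, a group chosen after its values were seen, 104 rose and 24 fell; their median GC content was 44.7%, against 50.4% in protein-coding genes, and 21 rose and 6 fell after the adjustment. Of 4 Y-linked genes, tested to check the samples, 3 rose over all genes tested and 4 adjusted over the list alone, but 0 passed after the adjustment. Their list level was 4.34, 4.18 and 4.25 log2 CPM in vehicle and 4.81, 4.68 and 4.68 in NTG (exact two-sided permutation p = 0.1, the smallest possible). The small nuclear RNA Rn7sk, chosen after its values were seen, was at 616 normalised reads in NTG replicate 1. In the other libraries it was at 4.12 to 29.7. In NTG replicate 1 the choroid plexus gene Ttr was at 415 against 2.18 to 19.8, and the pituitary gene Gh at 250.4 against 1303 to 3499.

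Log2 fold change was lower at higher transcript GC content, and the slopes per library, compared between groups, gave an exact p of 0.1, the smallest possible. A change in the shares of cell types would move the genes of a type together whatever their GC content, but within cell type lists Spearman's rho was -0.67 (bootstrap SD 0.04). Of the calls with a GC value, 24.3% passed in the same direction after removal of the smooth trends over GC content and length. The trends were fitted on a single reference transcript per gene, and bias that they do not describe may remain. The calls left therefore cannot exclude GC content and length as the whole source. GC-dependent recovery of reads in library preparation may be the source; rho was -0.32 over long non-coding genes, but this test was void because only 56.6% of them had a GC value. NTG itself and a difference in preparation between the groups cannot be told apart, because the labels give no batch that crosses the groups.

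Genes opposite a 20-fold higher gene fell more often than they rose: of 971 such genes 8 rose and 120 fell (median log2 fold change -0.15). The others did not pass. Of 194 genes overlapping a 20-fold higher gene on their own strand 2 rose and 6 fell. Of 16310 genes with neither kind of partner 2138 rose and 2238 fell (median 0.006). Against all genes with neither kind of partner, falls were thus not more frequent among the 971 genes, and rises were rarer. Among long non-coding genes alone, falls were more frequent opposite a 20-fold higher gene (3 rose and 83 fell of 690). Those with neither kind of partner also fell more often than they rose (41 rose and 114 fell of 1400). Of 108 that overlapped a 20-fold higher gene on their own strand, 1 rose and 1 fell. Reads of the higher gene counted on the other strand, in a share that differs between groups, are a candidate explanation: the medians differed by -0.17 (bootstrap SD 0.06), between the bounds set for and against it. At the median these genes held 1.42% to 1.53% of their partner's reads in vehicle libraries and 1.15% to 1.34% in NTG libraries. The 20-fold rule makes such shares small, and their difference restates the fall of these genes, so it is no separate support. GC content stays open too, since the median after adjustment was -0.066, but only 60.6% of these genes had a GC value, which made that test void. The antisense gene Gm46526, chosen after its values were seen, fell far more than the median of these genes and is not typical of them. It was at 991 ± 203 normalised reads in vehicle and 197 ± 50.8 in NTG (limma adjusted p = 0.000112).

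Interferon-stimulated genes passed camera as lower in NTG (adjusted p = 2.53e-05; adjusted p = 0.919 with an estimated correlation), though 4 of 28 members fell. Their level was highest in vehicle replicate 1 (4.73 log2 CPM), while vehicle replicate 3 (3.24) lay below NTG replicates 1 and 3 (3.37 and 3.29). More macrophages in that library are argued against by the macrophage list, which was only 0.165 log2 CPM above the mean of the other libraries (their SD 0.085), while the interferon list was 1.33 above. Whether vehicle replicate 1 alone makes the difference stays open: without it camera gave an adjusted p of 0.0572 and the median log2 fold change was -0.24, but camera gave 9.4e-05 after the GC and length adjustment (adjusted p = 0.77 with an estimated correlation and all libraries). Vehicle replicate 2 (3.90) also lay above every NTG library. Both camera values without vehicle replicate 1 assume a correlation of 0.01, whereas 0.89 was estimated for this list over all libraries. An interferon response in single samples and an effect of NTG were not separated by these values.

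The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 4512 genes past the threshold. It was the only 1 of the 10 splits with as many, and the highest of the others was 0. Each other split mixes NTG with vehicle libraries, so a difference between the groups widens its spread and lowers its gene count. Those gene counts therefore cannot show what chance gives. For gene lists the real split gave 3. Counting the real split, 8 of the 10 splits gave as many, and the highest of the others was 10. The camera calls at a preset correlation are to be read with these splits and with the estimated-correlation p values. With an estimated correlation the smallest camera adjusted p over the 40 lists was 0.919, and 0.77 after the GC and length adjustment. That version has few degrees of freedom with 3 against 3 libraries. A list that misses it is therefore not shown to be unchanged.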
